A study of Arabidopsis thaliana with 3 samples.

How the data were processed

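Leaf DNA of 3 Arabidopsis thaliana libraries was sequenced: the wild type WTa, the thm1_like pool (library T4) and the WTa_like pool (library T2), each with 1 library. DNA was extracted with CTAB, sheared and made into TruSeq libraries with limited-cycle PCR, per the labels' protocols. The genome build was TAIR10, per the submitters' processing notes. The aligner, the variant caller, the filters, the number of plants per pool, the mutagen and the cross are not given in the sources used here.

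The deposited table lists one variant site per line. It gives counts of reference and alternative reads and the depth of each pool, the depth and called allele of WTa, and the 2 SNP-index values as a fraction from 0 to 1, per the file headers. Reads were raw counts per site, and a check of all 1990 sites found depth equal to reference plus alternative reads. The deposited fraction matched the share of reads without the WTa allele at all 1990 sites within a rounding tolerance of 0.005: WTa carried the reference allele at 1912 sites and the alternative allele at 78. The deposited delta, T4 minus T2, differed from the recomputed one by at most 0.01. Every site had at least 7 reads in each pool and an index of at least 0.3 in one pool or both; whether these were the authors' filters is not given in the sources used here. Sites at which both pools have a low index are therefore not analysed here. No column of per-sample values was left without a sample.

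Delta was recomputed from the read counts as the thm1_like index minus the WTa_like index. Changes were classed from the WTa allele to the other allele as G-to-A, C-to-T, other substitution or indel. Means and SDs over sites were taken per chromosome and class, with bootstrap intervals from 10000 draws over sites; linked sites are not independent, so these intervals are too narrow as intervals for the chromosome. Windows of 1 Mb in steps of 100 kb with at least 5 sites were averaged, and the highest window was set against the highest windows of 10000 shuffles of the site values over the site positions. The candidate interval was the run of adjoining windows around the highest one above the 99th percentile of those shuffles. Single sites were compared with a two-sided Fisher's exact test on the reads of the pools, at sites with at least 10 reads in both pools, with Benjamini-Hochberg adjustment at 0.05. That left 1817 sites, 1816 of them nuclear. Shares of reads and sites have exact (Clopper-Pearson) 95% intervals, and a count of 0 is given the limit of 3 counts of the total.

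Median depth was 24 reads in the thm1_like pool (range 7 to 90), 23 in the WTa_like pool (7 to 94) and 12 in WTa (1 to 116). The tests were checked on simulated data. On counts simulated at the depths of the 1816 tested sites, with 200 sites changed, Fisher's exact test recovered 9.0% of sites with a delta of 0.3 and 93.0% of those with 0.6, with 3 false calls among 189 calls at 0.6, and made 0 calls with no site changed. The window scan placed its peak in a simulated linked block, past the 99th percentile, in 20 of 20 simulations over all sites and in 20 of 20 over G-to-A and C-to-T sites. Without a block it passed the 99th percentile in 0 of 20 and in 1 of 20. The block was 3 Mb long, with its G-to-A and C-to-T sites set to an index of 1 against 0.3, a strong difference. All other sites were drawn independently, without linkage and with no difference between the pools. The simulations therefore do not show how often linked regions that lean to 1 pool would pass.

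Genes were named from a RefSeq gene table of assembly TAIR10.1, whose chromosome identifiers are those of the deposited table. It gives gene bounds, not exons, and no genome sequence was used, so a site is placed inside the bounds of a gene or by its distance to the nearest protein-coding gene. The sites to be named were fixed by rule before the data were examined, as were the tests, windows, thresholds and the first set of alternatives. The rule took the 10 sites of largest delta in the candidate interval, the near-fixed sites that change a protein or a splice site, the site of highest delta on each other chromosome and the most negative site. Because the interval over all sites was empty, the first part was applied to the interval from G-to-A and C-to-T sites, and the share of G-to-A and C-to-T changes was computed in the highest window instead. The part on protein changes could not be applied; near-fixed sites within protein-coding bounds, the site of largest delta in the genome, sites near fixation in the WTa_like pool and tested sites on other chromosomes were named after their values were seen. One of the near-fixed sites of chromosome 4 within protein-coding bounds is counted but not named here.

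The alternatives were other window sizes, medians, site minimums, classes of sites, thresholds, read minimums, absolute delta, windows of 20 consecutive sites and sites thinned to one per 100 kb. Alternatives added after the data were seen were G-to-A sites alone, sites without another listed site within 200 bp (for windows and for the share of G-to-A and C-to-T changes), and Fisher's exact tests without indels or on G-to-A and C-to-T sites alone. With 1 library per group, no test between the groups across replicates, no test of other splits of the samples and no outlier test was made. The mitochondrial site was left out of all comparisons of nuclear sites. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.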

Results

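The series mapped the thm1 mutation of the plant Arabidopsis thaliana by bulked segregant analysis, in which plants of a segregating family are pooled by phenotype and the pools are sequenced as a whole. Genomic DNA from leaves of 3 libraries was sequenced: the wild-type library WTa, whose allele serves as the reference point at each site, a pool of thm1_like plants and a pool of WTa_like plants. Each group had 1 library, so no value has a replicate check. The table held 1990 variant sites, 1989 of them on the 5 nuclear chromosomes and 1 on the mitochondrial genome. Positions are those of the table, on the TAIR10 build. For each pool a site has a SNP-index, the share of reads that carry the allele WTa does not carry, and delta is the thm1_like index minus the WTa_like index. Mean depth over sites was 26.2 reads in the thm1_like pool (SD 12.8 over sites, total 52167), 24.9 reads in the WTa_like pool (SD 11.8, total 49615) and 13.0 reads in WTa (SD 6.02, total 25833). At the thm1_like median of 24 reads, an index of 0.5 has an exact (Clopper-Pearson) 95% binomial interval of 0.291 to 0.709, and a count of 0 allows a share of up to 12.5%. All intervals and limits from reads cover counting error only.

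The comparison of the pools asked which part of the genome separates thm1_like from WTa_like plants. Chromosome 4 stood apart. Its 160 G-to-A sites had a mean index of 0.764 in the thm1_like pool and 0.364 in the WTa_like pool, a mean delta of 0.40 (SD 0.269 over sites; 95% bootstrap interval over sites 0.357 to 0.441), and 147 of them were higher in the thm1_like pool. The first part of chromosome 4, from position 613008 to about 5.06 Mb, held 28 sites that were near fixation in the thm1_like pool and at a mean index of 0.265 in the WTa_like pool (SD 0.0983). That mean is bounded by the choice of these 28 sites, at an index of at least 0.9 in the thm1_like pool and at most 0.5 in the WTa_like pool. Sites of lower index lay among them, and over the 16 G-to-A and C-to-T sites from 4 to 5 Mb the mean thm1_like index was 0.561 (SD 0.357). The longest run of G-to-A sites at an index of 1, uninterrupted by another G-to-A site, lay inside this stretch: 8 sites from 1820256 to 2358085, a stretch of 538 kb that contains 51 protein-coding genes. The run covers 233 thm1_like reads, none with the WTa allele by the way it was chosen, so no limit for the region follows from this count. At the next G-to-A site, 2509581, 26 of 30 thm1_like reads lacked the WTa allele. The WTa_like pool had a mean index of 0.272 over the 8 sites (SD 0.0783).

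Over all sites, the mean delta of chromosome 4 was 0.200 (SD 0.345, 300 sites). Chromosome 1 had 0.0225 (489 sites), chromosome 2 had 0.0322 (299 sites), chromosome 3 had 0.0770 (460 sites) and chromosome 5 had -0.0774 (441 sites). Of the 93 nuclear sites with a delta of at least 0.5, 63 lay on chromosome 4, against 13 on chromosome 1, 3 on chromosome 2, 11 on chromosome 3 and 3 on chromosome 5. A delta of -0.5 or lower occurred at 28 sites, 4 of them on chromosome 4.

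**Figure D1:**
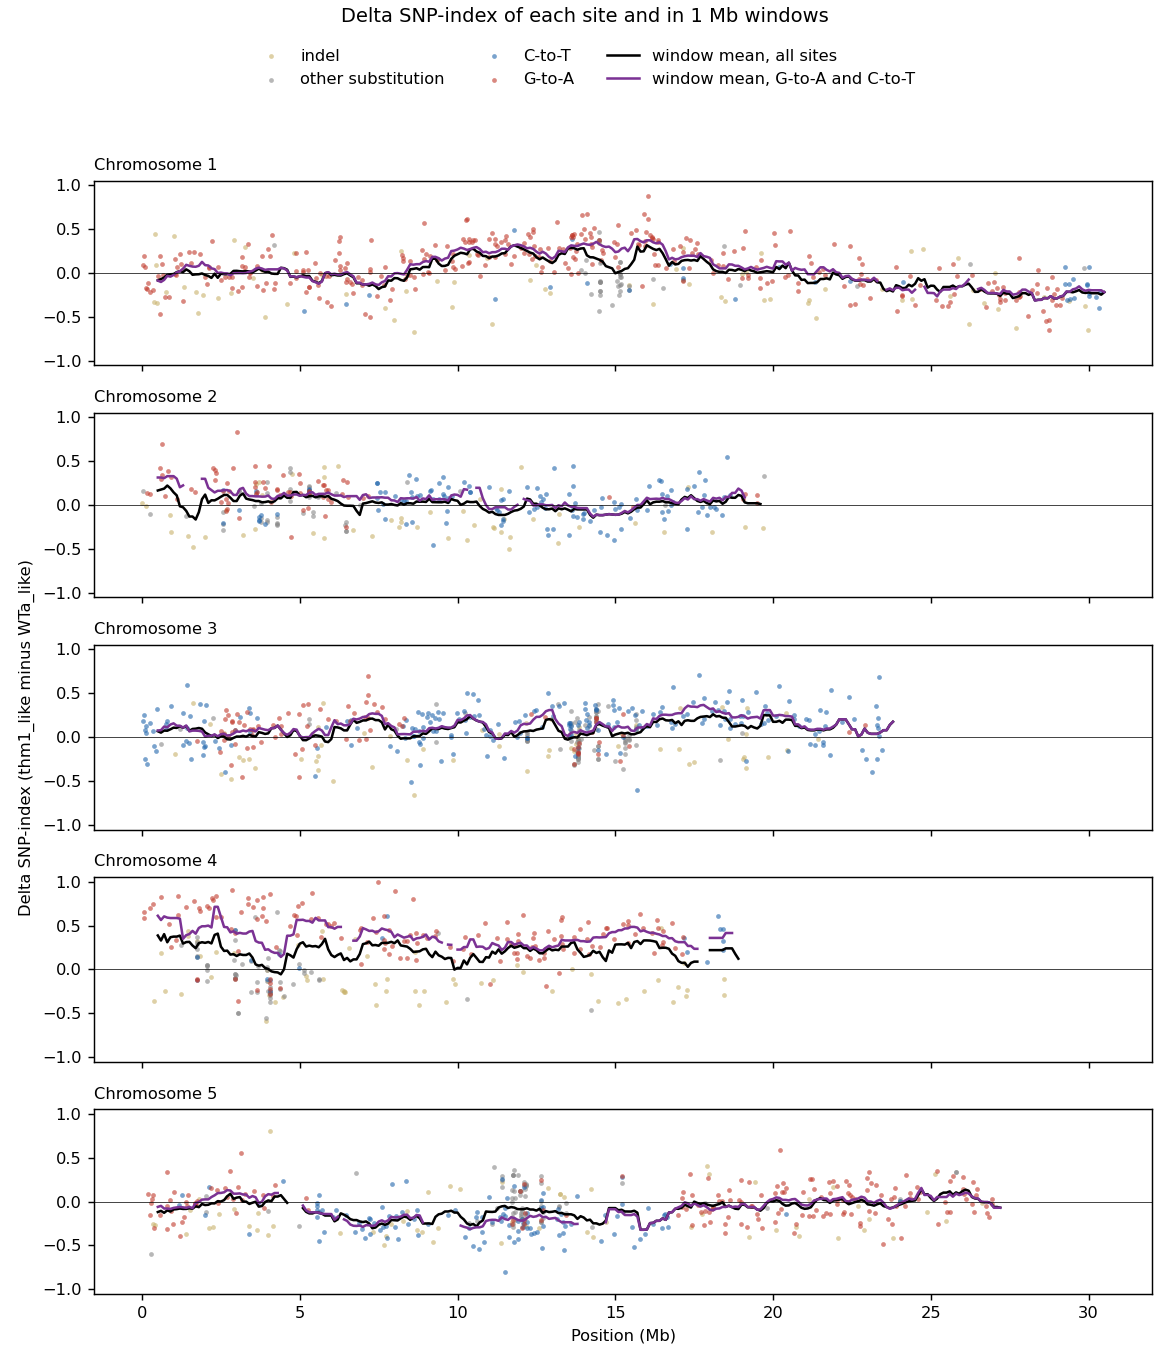
Delta SNP-index (thm1_like minus WTa_like) of each nuclear site against its position in Mb, 1 panel per chromosome, coloured by class of change; the black line is the mean of 1 Mb windows over all sites and the purple line that over G-to-A and C-to-T sites. The purple line reaches 0.713 at 1.8 to 2.8 Mb of chromosome 4 and stays at or below 0.387 on the other chromosomes.

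In windows of 1 Mb moved in steps of 100 kb, the highest mean delta over all sites lay at 1.9 to 2.9 Mb of chromosome 4. Its 16 sites had a mean delta of 0.408 (SD 0.378), with a mean index of 0.709 in the thm1_like pool and 0.302 in the WTa_like pool. A window as high appeared somewhere in the genome in 361 of 10000 shuffles of the site values over the site positions. This window was above the 95th percentile of the shuffled highest windows (0.396) and below the 99th (0.450), so the candidate interval as defined at the 99th percentile was empty. With G-to-A and C-to-T sites alone, the highest window lay at 1.8 to 2.8 Mb of chromosome 4, with 9 sites and a mean delta of 0.713 (SD 0.0853), and 1 of 10000 shuffles gave a window as high. Its mean index was 0.985 in the thm1_like pool and 0.272 in the WTa_like pool. In that scan 20 windows passed the 99th percentile (0.536), all on chromosome 4 between 0 and 6.3 Mb. The run around the highest one extended from 1.8 to 3 Mb. Most of the 20 lay outside this run, from 0 to 1.7 Mb (up to 0.611) and between 4.4 and 6.3 Mb (up to 0.587). At the 95th percentile (0.476), 34 windows passed in that scan, all on chromosome 4, the last ending at 16.2 Mb. The run therefore does not delimit the region that separates the pools. The shuffles describe how sites cluster in these 2 libraries and ignore linkage between neighbouring sites.

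The interval of 1.8 to 3 Mb on chromosome 4 held 33 sites, 13 of them G-to-A, and the bounds of 155 protein-coding genes. Because the scan over all sites left no interval, the sites named next were taken from the interval of the scan over G-to-A and C-to-T sites, a choice made after the scan was seen. The 10 sites with the largest delta were all G-to-A changes, and the thm1_like index was 1 at 9 of them. Within protein-coding bounds, position 2229834 lay where PMP22 (AT4G04470), which encodes a peroxisomal membrane protein, overlaps AT4G04480. All 21 thm1_like reads there lacked the WTa allele, as did 4 of 21 WTa_like reads (delta 0.810, adjusted p = 5.02e-06 by Fisher's exact test). Position 2126019 lay in AT4G04340, a gene with the synonym osca1 whose name refers to the calcium rise under hyperosmotic stress, with 32 of 32 against 11 of 37 reads (delta 0.703, exact adjusted p = 7.12e-08). Position 2509581 lay in DES-1-LIKE (AT4G04930), listed as a transmembrane protein, with 26 of 30 against 10 of 37 reads (delta 0.596, exact adjusted p = 9.32e-05). The pools differed more at position 2849135 in the pseudogene AT4G05581, where 21 of 21 against 2 of 21 reads lacked the WTa allele (delta 0.905, exact adjusted p = 2.85e-07).

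Pseudogenes held 3 more of these 10 sites. They were position 1820256 in AT4G03873, with 44 of 44 against 14 of 46 reads (delta 0.696, exact adjusted p = 1.97e-10), position 1824758 in AT4G03876 (delta 0.667) and position 2358085 in AT4G04655 (delta 0.60, with only 10 WTa_like reads). The other 3 lay outside annotated gene bounds. Position 2333489 was 675 bp from AT4G04630 (delta 0.833), position 2245140 was 210 bp from CRK38, a cysteine-rich receptor-like kinase gene (34 of 34 against 3 of 14 reads, delta 0.786), and position 2049027 was 5010 bp from AT4G04260 (delta 0.727). All 10 passed the adjusted threshold of 0.05, which follows largely from their choice by large delta on the same reads. With exons and the genome sequence not used here, no site could be assigned to a codon, an intron or a splice site.

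**Figure D2:**
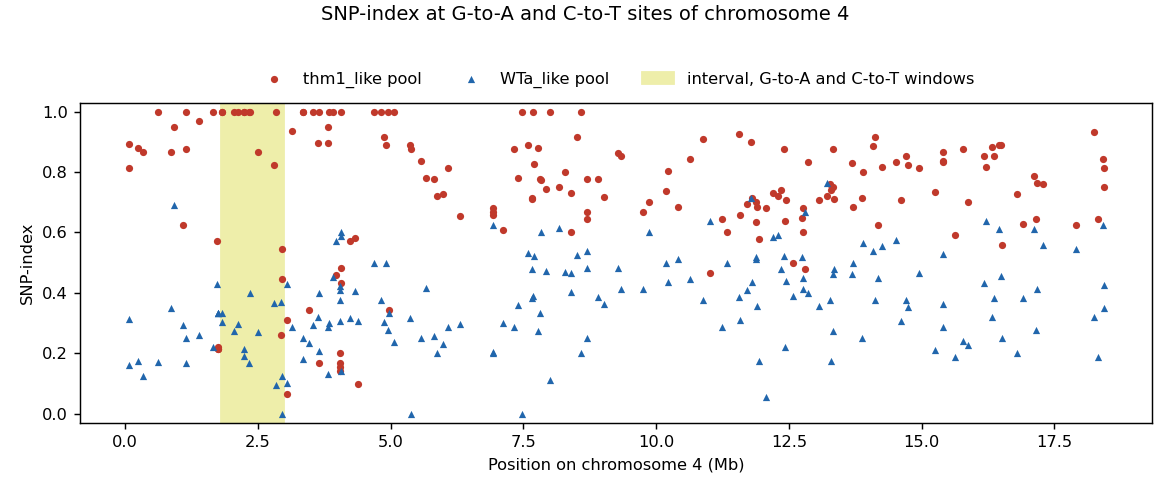
SNP-index of each G-to-A and C-to-T site of chromosome 4 against position in Mb, with circles for the thm1_like pool and triangles for the WTa_like pool; the shaded band is the interval of 1.8 to 3 Mb. From 2 to 3 Mb, 7 of the 12 sites sit at an index of 1 in the thm1_like pool, while the WTa_like pool has a mean index of 0.231 there (SD 0.122).

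Sites near fixation in the thm1_like pool (index of at least 0.9) and at an index of at most 0.5 in the WTa_like pool numbered 40 in the genome, and 36 of them lay on chromosome 4. The opposite arrangement was found at 3 sites, named after their values were seen: an indel at 11089167 of chromosome 1, 578 bp from GlcNAc1pUT1 (delta -0.583), a substitution at 277365 of chromosome 5 in SCAR4 (delta -0.60), and 11505469 of chromosome 5 in the pseudogene AT5G30410 (delta -0.80). On chromosome 4, 34 of the 36 were G-to-A changes, 28 had no thm1_like read with the WTa allele, and 764 of the 776 thm1_like reads over them carried the other allele. The WTa_like pool had a mean index of 0.266 at these sites (SD 0.109). The limits of 0.9 and 0.5 that chose the sites bound both that share of reads and this mean. Protein-coding bounds held 14, pseudogenes 10, and 12 lay outside gene bounds.

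Coding effects could not be assigned, so the genes of this list are named after their values were seen. In the first part of chromosome 4, MLO1 (AT4G02600), a member of the family of powdery mildew susceptibility genes, had 32 of 32 thm1_like reads against 3 of 18 WTa_like reads without the WTa allele at position 1146618 (delta 0.833). AT4G03120 had a delta of 0.708 at 1386002, AT4G06534 a delta of 0.818 at 3357746 and AT4G06744 a delta of 0.857 at 4071470. Farther along the chromosome, AT4G12690 at 7481346 had the largest delta of the genome (1.00), from 10 of 10 against 0 of 7 reads, where a count of 0 of 7 allows a share of up to 42.9%. RLP47, a receptor-like protein gene, had a delta of 0.889 at 8005405, also from fewer than 10 WTa_like reads. Other genes there included AT4G15040 (8582434, delta 0.80), the beta-glucosidase gene BGLU47 (11563443, delta 0.539) and AT4G28570 (14120245, delta 0.542). The receptor kinase gene GSO1, which acts in the Casparian strip of the root endodermis, had a delta of 0.534 at 10885686 from 10 of 11 against 3 of 8 reads, and SEC14 had a delta of 0.612 at 18245838. The sites in AT4G12690, RLP47 and GSO1 had too few WTa_like reads to be tested. Outside chromosome 4, the near-fixed sites were in the organellar DNA polymerase gene POLGAMMA1 on chromosome 3 (7170362, delta 0.694), in AT5G49770 on chromosome 5 (20226554, delta 0.591), in the pseudogene AT3G47875 (17664235, delta 0.714) and 3993 bp from AT3G28170 on chromosome 3 (10494184, delta 0.491).

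Read counts at single sites were compared with Fisher's exact test (two-sided, Benjamini-Hochberg adjustment), which compares these 2 libraries and not the conditions. Of 1816 nuclear sites with at least 10 reads in both pools, 229 passed an adjusted p of 0.05, 149 higher and 80 lower in the thm1_like pool. Of the 80 lower sites, 42 were indels. Without indels, a choice made after the data were seen, 138 sites were higher and 37 lower. On G-to-A and C-to-T sites alone, also chosen afterwards, 139 were higher and 33 lower, and with Bonferroni adjustment over all sites 35 were higher and 2 lower. Chromosome 4 had 90 of its 267 tested sites past the threshold, 79 higher and 11 lower. Among its 140 tested G-to-A sites, 69 passed and all 69 were higher in the thm1_like pool, and the same held for 6 of 17 C-to-T sites. Chromosome 1 had 66 such sites (41 higher, 25 lower), chromosome 2 had 17 (9 higher, 8 lower), chromosome 3 had 26 (18 higher, 8 lower) and chromosome 5 had 30 (2 higher, 28 lower). Indels made up 7 of the 8 lower sites of chromosome 2 and 8 of the 11 of chromosome 4, and 13 of the 25 of chromosome 1, 4 of the 8 of chromosome 3 and 10 of the 28 of chromosome 5. The 2 higher sites of chromosome 5, named after their values were seen, were 20226554 in AT5G49770 and an indel at 17917988 in the calmodulin-like gene CML43 (delta 0.40). In simulated counts at the same depths, 93.0% of sites with a true delta of 0.6 were recovered but only 9.0% of those with 0.3. In that simulation a delta near 0.3 was therefore mostly not detectable at a single site. The simulation at 0.3 made 19 calls, against 229 in the data, and the adjusted threshold is stricter where fewer sites pass. The 9.0% can therefore understate detection in the data.

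Away from chromosome 4, both directions of change occurred, with smaller windows. Over G-to-A and C-to-T sites, the highest windows were 15.2 to 16.2 Mb of chromosome 1 (mean delta 0.387, SD 0.264, 16 sites), 0.3 to 1.3 Mb of chromosome 2 (0.330, SD 0.193, 8 sites) and 17.3 to 18.3 Mb of chromosome 3 (0.369, SD 0.171, 8 sites). The lowest were 15.3 to 16.3 Mb of chromosome 5 (-0.321, SD 0.155, 6 sites) and 27.8 to 28.8 Mb of chromosome 1 (-0.314, SD 0.199, 13 sites). None of the highest windows of these 4 chromosomes passed the 95th percentile of the shuffled highest windows (0.476). That limit includes windows of as few as 5 sites and is strict for windows of more sites. Over all sites, the 99th percentile was 0.450, but 0.367 with at least 10 sites per window and 0.305 with 20 consecutive sites. The highest window of chromosome 1 over all sites, 15.5 to 16.5 Mb, had 0.317 over 21 sites. Not passing therefore does not show a chance order in these regions. The lowest windows were not set against shuffles.

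The site with the largest delta on chromosome 1 was 16035993 in the pseudogene AT1G42655, with 15 of 17 against 0 of 7 reads (delta 0.882). On chromosome 2 it was 3012478, 145 bp from AT2G07240, with 10 of 12 against 0 of 8 reads (delta 0.833). On chromosome 3 it was 17664235 in the pseudogene AT3G47875, with 10 of 10 against 2 of 7 reads (delta 0.714). On chromosome 5 it was an indel at 4063723 in MYB46 (AT5G12870), a transcription factor of secondary wall formation, with 12 of 15 against 0 of 7 reads (delta 0.80). WTa had only 1 read at this indel, so the sign of its delta rests on that read. The most negative delta of the genome was -0.80 at 11505469 of chromosome 5, in the pseudogene AT5G30410, with 2 of 10 against 7 of 7 reads. Each of these 5 sites had fewer than 10 WTa_like reads and was not tested. A count of 0 of 7 allows up to 42.9%, and 0 of 8 up to 37.5%. The allele called in WTa rested on few reads at other named sites too. WTa had 3 reads at 11089167 of chromosome 1 and at the site named in AT5G17040. It had 4 reads at 11505469 of chromosome 5 and at the sites named in AT4G06744, AGO3 and AT1G76580. The signs of delta at these sites rest on those reads.

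Among tested sites in protein-coding bounds on these chromosomes, named after their values were seen, SKIP3 on chromosome 2 had 9 of 13 against 0 of 15 reads (617485, delta 0.692, exact adjusted p = 0.00348), where 0 of 15 allows up to 20.0%. HMT2, a homocysteine methyltransferase gene on chromosome 3, had 14 of 17 against 2 of 15 reads (23371804, delta 0.690, exact adjusted p = 0.00653). PHS1 on chromosome 3, which encodes a pyrimidine reductase of riboflavin synthesis, had a delta of 0.403 at 17462278 (exact adjusted p = 0.0184). The Argonaute gene AGO3 on chromosome 1 had a delta of 0.390 at 11188456 (exact adjusted p = 0.00991). Lower in the thm1_like pool were AT1G76360 on chromosome 1 (28643379, delta -0.547, exact adjusted p = 0.00183), the microtubule-associated protein gene MOR1 on chromosome 2 (14971313, delta -0.396, exact adjusted p = 0.0112) and the anion channel gene SLAH3 on chromosome 5 (8120266, delta -0.421, exact adjusted p = 0.0240). No fixed rule chose these genes. Others that passed include AT3G54510 on chromosome 3 (20180887, delta 0.586), AT1G76580 on chromosome 1 (28735847, delta -0.644) and AT5G17040 on chromosome 5 (5606388, delta -0.453).

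The classes of change moved differently. Of the nuclear sites, 841 (42.3%) were G-to-A, 527 (26.5%) C-to-T, 312 (15.7%) other substitutions and 309 (15.5%) indels, read from the WTa allele to the other allele. On chromosome 4 the mean delta was 0.40 for G-to-A and 0.209 for the 19 C-to-T sites (SD 0.253), against -0.0318 for the 60 other substitutions (SD 0.262) and -0.100 for the 61 indels (SD 0.249). Indels had a negative mean delta on each chromosome, from -0.152 on chromosome 1 to -0.0800 on chromosome 3. In the Fisher's exact tests 45 of 274 indels passed, 3 higher and 42 lower in the thm1_like pool. The 3 higher ones, named after their values were seen, were the one in CML43 and those at 5706979 (delta 0.433) and 16449310 (delta 0.476) of chromosome 4, outside gene bounds. C-to-T sites had a mean delta of 0.136 on chromosome 3 and -0.203 on chromosome 5.

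**Figure D3:**
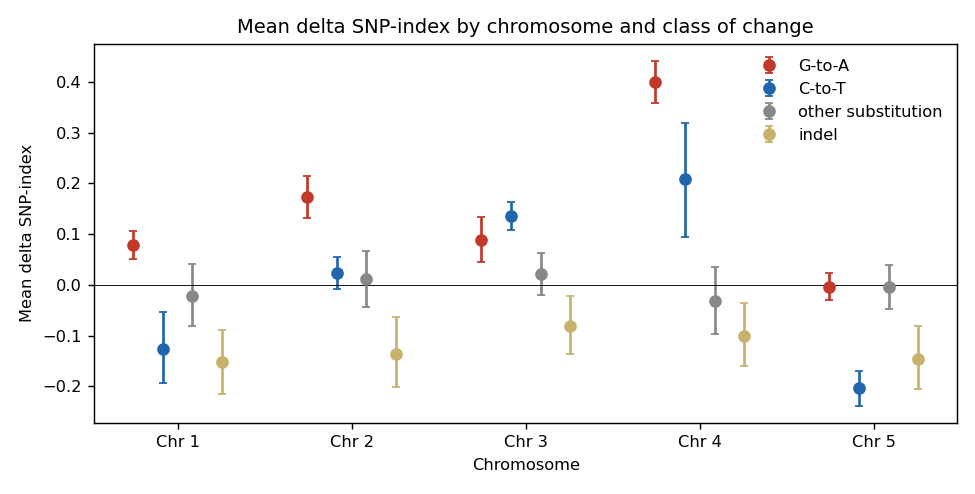
Mean delta SNP-index (thm1_like minus WTa_like) of the sites of each class on each nuclear chromosome; bars are 95% bootstrap intervals over sites, which treat linked sites as independent. G-to-A sites of chromosome 4 have the highest mean, 0.40, and indels lie below 0 on all 5 chromosomes.

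The G-to-A and C-to-T classes were spread unevenly along the chromosomes. Chromosome 1 had 342 G-to-A and 32 C-to-T sites and chromosome 4 had 160 and 19, while chromosome 3 had 85 and 229. On chromosome 2, the stretch from 8 to 14 Mb held C-to-T sites and no G-to-A site, and on chromosome 5 the bin from 22 to 24 Mb held 31 G-to-A sites and no C-to-T site. The share of substitutions that were G-to-A or C-to-T was 64.3% in the highest window over all sites, 1.9 to 2.9 Mb of chromosome 4 (9 of 14 substitutions, exact 95% interval 35.1 to 87.2%), and 81.6% elsewhere (79.6 to 83.4%, 1666 substitutions), so the 2 intervals overlapped. In the interval of 1.8 to 3 Mb it was 48.3% (14 of 29, 29.4 to 67.5%) against 82.0% elsewhere (80.1 to 83.8%), but 12 of its 15 other substitutions lay within 200 bp of another listed site, and the exact intervals treat such sites as independent. Without clustered sites, a setting added after the data were seen, the share was 78.6% in this interval (11 of 14, 49.2 to 95.3%) against 92.6% elsewhere (91.1 to 94.0%), and the intervals overlapped. In the highest window it was then 90% (9 of 10, 55.5 to 99.7%).

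**Figure D4:**
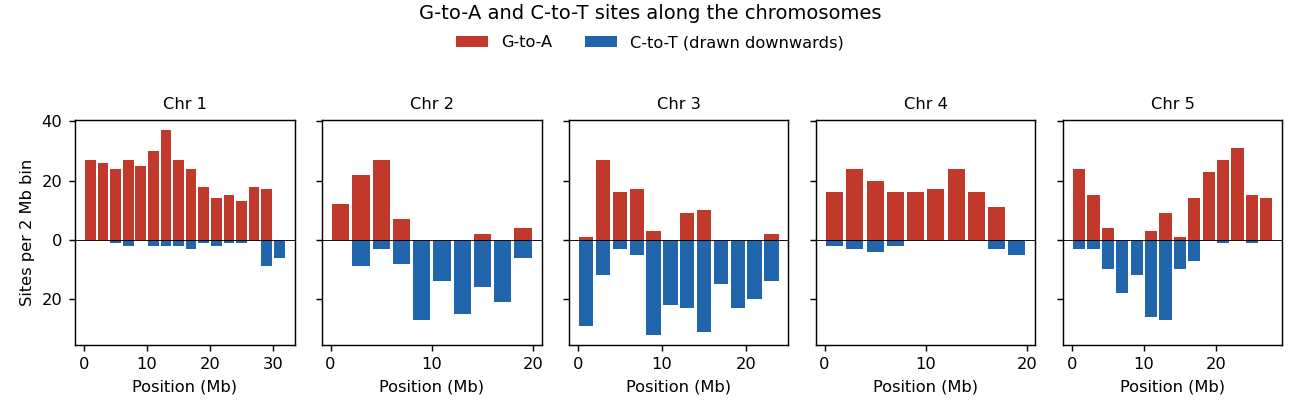
Number of G-to-A sites (upwards) and C-to-T sites (downwards) in 2 Mb bins along each nuclear chromosome, with position in Mb. Long stretches hold almost only 1 of the classes, such as 8 to 14 Mb of chromosome 2 with C-to-T sites alone.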

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

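The single mitochondrial site was set aside from the nuclear comparisons, and its values were looked at only after the table was seen; no test was run on it. At position 9557 of the mitochondrial genome, 9 of 27 thm1_like reads (33.3%, exact 95% interval 16.5 to 54.0%) and 16 of 55 WTa_like reads (29.1%, 17.6 to 42.9%) lacked the allele called in WTa, which had 116 reads there. No biological explanation was tested.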

How the results depend on the processing

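The settings with G-to-A sites alone, without sites within 200 bp of another site (for windows and for the share of G-to-A and C-to-T changes), and the Fisher's exact tests without indels or on G-to-A and C-to-T sites alone were chosen only after the results were seen; the others were planned. The highest window lay on chromosome 4 under all alternatives run. Its mean delta passed the 99th percentile of shuffles, unlike the main 0.408, with 0.5 Mb windows (0.637), medians (0.596), at least 10 sites per window (0.408), G-to-A and C-to-T sites (0.713), no indels (0.611), absolute delta (0.511), windows of 20 consecutive sites (0.407), G-to-A sites alone (0.713) and no clustered sites (0.532). It did not with 2 Mb windows (0.350) or at least 10 reads in both pools (0.408). Without indels the peak moved to 0 to 1 Mb of chromosome 4, and with absolute delta to 0.2 to 1.2 Mb. The interval, 0 Mb long in the main scan, was then 0.6 Mb (0.5 Mb windows), 1.1 Mb (medians), 1.1 Mb (at least 10 sites), 1.2 Mb (G-to-A and C-to-T), 1.7 Mb (no indels, from 0 to 1.7 Mb), 1 Mb (absolute delta), 1.19 Mb (20 consecutive sites), 1.2 Mb (G-to-A alone), 1.6 Mb (no clustered sites) and 1 Mb at the 95th percentile. The position of the peak within the first 3 Mb of chromosome 4 therefore depended on which sites were averaged and on whether the sign of delta was kept; the cause was not tested.

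Sites of large delta, 93 in the main setting, numbered 55 at 0.6 and 175 at 0.4, as looser or stricter limits must give. The near-fixed list of 40 grew to 91 with a thm1_like index of at least 0.8, 75 of them on chromosome 4. Fisher's exact test called 37 sites with Bonferroni instead of 229, 34 of them on chromosome 4, and 35 higher and 2 lower in the thm1_like pool instead of 149 and 80. Without indels the split was 138 and 37, and on G-to-A and C-to-T sites alone 139 and 33. The share of G-to-A and C-to-T changes in the highest window, 64.3% over all substitutions, was 90% without clustered sites. Over the 10 named sites of the interval, 46 of 47 adjusted p-values of Fisher's exact test under alternatives stayed on the same side of the threshold. These alternatives reused the same reads and changed only the adjustment or the sites adjusted over. The direction could therefore not change, and the agreement says little about robustness. Positions 2245140, 1824758 and 2358085 had fewer than 20 WTa_like reads and were left out at the 20-read minimum. With Bonferroni, position 2358085 no longer passed (exact adjusted p = 0.196). Mean deltas moved beyond their intervals with G-to-A and C-to-T sites on chromosomes 1 (0.0611), 2 (0.0782), 3 (0.123) and 4 (0.380), with medians on chromosomes 2 (0.0702), 3 (0.104) and 5 (-0.100), and with thinned sites on chromosomes 3 (0.113), 4 (0.284) and 5 (-0.102). Absolute deltas, which ignore the sign, were 0.222, 0.184, 0.197, 0.336 and 0.192 on chromosomes 1 to 5. Signed means kept their sign under every alternative run, and the cause of the shifts was not tested. The threshold alternative that needed a deposited threshold column was not run, since the table used here has none. No paired analysis was possible because each group had 1 library.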

Other observations

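The tests of low depth for indels and of a strand bias of calling were written down before their results were seen; the other tests of this part, and the regions, were chosen only after. Outside chromosome 4, several long regions leaned to 1 pool over their G-to-A and C-to-T sites. On chromosome 1, 117 of 127 sites from 10 to 18 Mb were higher in the thm1_like pool (mean delta 0.282, SD 0.194), while 61 of 68 sites from 23 to 31 Mb were lower (-0.218, SD 0.162). On chromosome 5, 108 of 125 sites from 5 to 17 Mb were lower (-0.199, SD 0.191), and on chromosome 3, 43 of 45 sites from 16 to 21 Mb were higher (0.267, SD 0.176). The rest of chromosome 4, from 6 to 19 Mb, was higher at 107 of 110 sites (0.345, SD 0.187). The number of plants per pool is not given in the sources used here, so the chance spread of unlinked regions between pools could not be computed.

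G-to-A and C-to-T sites lay in long blocks. Along the chromosomes, adjoining sites of these classes switched class 172 times among 1368 sites, against 405 to 507 switches in 10000 shuffles within chromosomes, which argues against a chance order. Without sites within 200 bp of another, 104 switches remained among 1266 sites, against a lowest value of 347 in 2000 shuffles. A strand bias of calling that affects every transition was predicted to give the same blocks in A-to-G and T-to-C sites. These switched 57 times among 118 sites, near the shuffled median of 56, and so showed no such blocks. The comparison cannot exclude a strand bias, since it was not tested whether such a bias would act in blocks along a chromosome. Clustered sites were also kept in it, and 67.0% of all other substitutions lay within 200 bp of another listed site. The majority class held a median of 93.8% of sites over 62 bins of 2 Mb, with 53.3% in the lowest bin. What gave rise to the blocks stays open: the mutagen is not given in the labels, and neither a bias limited to G and C nor a biological explanation was tested.

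Substitutions other than G-to-A and C-to-T did not shift with their neighbours on chromosome 4. Mutations of the other parental chromosome would have an index near 0 where the thm1_like pool is near fixation. The 52 other substitutions inside the near-fixed block had a median thm1_like index of 0.328 (95% bootstrap interval 0.270 to 0.442), which argues against this explanation. The bootstrap treats the sites as independent, although many lie within 200 bp of another, so the interval is too narrow. Reads shared between near-identical sequence copies stay open as a candidate explanation: on chromosome 4, 65.0% of the 60 other substitutions lay within 200 bp of another listed site against 10.6% of the 179 G-to-A and C-to-T sites, a difference of 54.4 percentage points. That test was first run over all chromosomes, where the shares were 67.0% and 7.46%, and was limited to chromosome 4 afterwards. No biological explanation beyond the linkage in repulsion was tested.

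Indels had a lower index in the thm1_like pool (mean 0.252) than in the WTa_like pool (0.375). Linkage to the region on chromosome 4 would leave indels of the other chromosomes near 0, but these 248 indels had a mean delta of -0.129 (95% bootstrap interval -0.160 to -0.0960), which argues against it as the whole cause. Low depth in the thm1_like pool was also argued against, since the 37 indels with at least 30 reads in both pools had a mean delta of -0.144 (-0.198 to -0.0858). A library-wide difference in how indel reads arise or align stays open as a candidate explanation: the delta of indels followed the mean delta of G-to-A and C-to-T sites within 500 kb with a slope of 0.151 (0.0121 to 0.295, 304 indels), against 0.889 (0.827 to 0.95) for G-to-A and C-to-T sites themselves. With 1 library per pool, the library and the phenotype of the pool cannot be separated by these data.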
